A study of Mus musculus with 6 samples.

How the data were processed

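Small RNA libraries of sperm from 8-week-old wild-type C57BL/6 males were analysed, 3 from control and 3 from microplastic-exposed males, with groups taken from the treatment label and replicate numbers from the sample titles. The deposited file names number the microplastic libraries 2, 3 and 4 where the titles give 1, 2 and 3, and the growth text names the particles for every sample, controls included. Per the labels' protocols, RNA was extracted with Trizol, RNA of 15 to 50 nt was cut from a gel, treated with T4 polynucleotide kinase and then AlkB, and made into libraries with the NEBNext small RNA kit. The deposited values are raw counts: each file gives unique sequences and their number of reads, with no annotation and no normalization, and the sequences are 15 to 45 nt long. The files hold collapsed sequences, so the reads had been trimmed before deposit. The submitters' processing notes name the mm10 build without a role, and the aligner and trimmer are not given in the sources used here. Counts carry no molecular identifiers, so copies made by PCR are counted as reads. The depth was between 19341637 and 28433836 reads per library, and no pair of libraries of 1 group agreed within sampling noise (chi-square per degree of freedom from 16.6 to 46.8 over features), so none was treated as a repeat deposit of another library.

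Sequences were matched to reference RNAs in the sense direction without mismatches, over their whole length, from 15 nt for small RNAs and from 20 nt for long transcripts. Transcripts and gene positions came from the GENCODE M21 annotation of GRCm38. This reference lacks most rRNA and all nuclear tRNA genes, so the 18S, 5.8S and 28S sequences were assembled from the reads themselves (28S in 3 pieces of 259, 2409 and 1651 nt, 18S of 1871 nt and 5.8S of 157 nt), and a panel of 52 nuclear tRNA sequences was written from memory and kept where its stems paired and reads tiled it, which left 47. Assembly extended by words of 18 nt with at least 8 reads per step. Both steps were decided after the files had been seen and before any comparison of groups, and tRNA isodecoders outside the panel were not used here. Positions in assembled rRNA count from the first base of the piece. A tRNA fragment is a 5′ fragment if it starts within the first 3 nt, a CCA-end fragment if it ends in the added CCA, a 3′ fragment if it ends at the last base before the CCA or up to 2 nt short of it, and otherwise internal. Sequences with parents in several classes went to 1 class in the order miRNA, rRNA, nuclear tRNA, mitochondrial tRNA, Y RNA, small nucleolar RNA, small nuclear RNA, lncRNA, mRNA and other, and a sequence with several parents of 1 class formed a joint feature. The class and feature rules depend on this reference: 3 miRNA features share over 90% of their reads with rRNA or tRNA, and fragments of rRNA embedded in long transcripts can be counted under genes such as Tmem38b. Unannotated sequences include variants of abundant RNAs with 1 mismatch. piRNAs, for which no reference was used, stay among mRNA, lncRNA or unannotated sequences.

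Features and unique sequences were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with trimmed-mean (TMM) scaling, the filterByExpr filter and Benjamini-Hochberg adjustment at 0.05. TMM factors ran from 0.690 to 1.58, with control replicate 2 highest and microplastic replicate 3 lowest. Every microplastic factor lay below every control factor. Classes were tested with the total reads as library size. Shares, ratios and lengths were compared by two-sided exact permutation tests of group means over all 20 arrangements, so no p could fall below 0.1, and were adjusted within each family. Lists of features fixed before the data were examined, 22 that could be formed, were tested with camera in limma 3.58.1 with a correlation of 0.01, on log2 CPM with a prior count of 2, and again with an estimated correlation and with fry; 18 had enough members. They were the family of miR-34 and miR-449, the X-linked testis cluster, the let-7, miR-17-92 and miR-30 families, the group of miR-10, miR-99, miR-100 and miR-125, the Dlk1-Dio3 cluster, miRNAs of epithelium, muscle, blood cells and of endothelium, stroma and liver, miRNAs of published paternal stress and diet work, 5′ tRNA fragments of mature sperm, all 5′ and all 3′ nuclear tRNA fragments, mitochondrial tRNA fragments, cytoplasmic and mitochondrial rRNA fragments, Y RNAs, small nucleolar RNAs, small nuclear RNAs and miRNAs. A further 4 lists of mRNAs (late spermatid, epididymal epithelium, immune cell and immediate-early response) were written after the data had been seen and are reported in the closing section only.

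Features to name were fixed before the data were examined: called features with at least 10 CPM and no overlap of groups, the 2 most abundant features of each small RNA class, the most abundant members of each list and, where fewer than 5 were called, the 5 with the smallest p in each direction. For sequences the rule took, of rRNA fragments, tRNA fragments (nuclear and mitochondrial together) and miRNAs, the 2 most abundant called ones per direction, and the 5 most abundant of all. Of the called sequences the rule took, 1 is not reported here. The feature test was tested on simulated data with the same 11010 features. At each of 4 sizes 50 were changed, drawn only from those with a mean of at least 10 CPM. It recovered 24% of 2-fold changes and 100% of 4-fold, 8-fold and 16-fold changes, with 21 false calls. On 56602 simulated sequences it recovered 0% of 2-fold, 30% of 4-fold, 92% of 8-fold and 100% of 16-fold changes, with 3 false calls. The changed sequences also had a mean of at least 10 CPM, so recovery of changes below 10 CPM was not tested. Camera called a simulated shift of the small nucleolar RNAs and 0 of 17 other lists. The simulated features varied independently of each other, so this does not show how often camera calls unchanged lists whose members move together.

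Alternatives were DESeq2 1.42.0, limma-voom, RLE, upper-quartile and total-read scaling, no filter, a minimum of 100 reads, the replicate number as a block, leaving out each library, splitting joint features, tRNA features without the end, other denominators, sequences of several classes left out, sequences seen once left out, and unique sequences for lengths. Added after seeing the data were a reference without the assembled rRNA and the tRNA panel, 1 mismatch to rRNA and tRNA, exact matches only, removal of a trend on length and GC content per library, the pair of libraries with extreme TMM factors left out, the added lists without members seen before and as shares of all reads, and weights that give mRNA fragments of 20 nt or more 1 length profile in every library. Also after the data were seen, called sequences outside rRNA were searched for a stretch of 15 nt shared with rRNA. Reads of Tmem38b, nearly all of which hold such a stretch of 5S, stayed among mRNA fragments. The length weights were therefore also made without mRNA fragments that share such a stretch with rRNA. Restriction to sequences marked as matching the genome was not run because the files carry no such mark. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.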

Results

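Small RNAs of mouse sperm were sequenced by PANDORA-seq after oral exposure of the males to polystyrene microplastics. In this assay RNA is treated with T4 polynucleotide kinase, which repairs fragment ends, and then with AlkB, a demethylase that removes base methylations which stop reverse transcription. Fragments of tRNA and rRNA thus enter the library more readily than in a standard small RNA protocol. There were 3 control libraries from wild-type C57BL/6 males given water and 3 microplastic libraries from males given 10 mg per kg body weight per day of particles of 1.1 µm mean size for 4 weeks. A low cholesterol diet is listed for both groups. The control libraries held 24253227, 28433836 and 19341637 reads and the microplastic libraries 21068912, 28259043 and 19356107 reads, each as unique sequences of 15 to 45 nt. The comparison of the groups asks which small RNAs of sperm differ after exposure of the male. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these samples, which may be technical.

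Fragments of rRNA made up most of the sperm reads in both groups, with 63.7% ± 3.53 (SD, n = 3) in control and 66.2% ± 3.89 in microplastic libraries. Fragments of nuclear tRNA, the class most often linked with paternal effects, took 3.81% ± 1.02 in control and 4.71% ± 0.216 in microplastic libraries, and the groups overlapped. Mitochondrial tRNA fragments took 0.101% ± 0.0121 in control and 0.0612% ± 0.0121 in microplastic libraries, with every microplastic library below every control library. The same order was seen for miRNA, the silencing RNAs processed by Dicer, at 0.0526% ± 0.0141 in control and 0.0369% ± 0.00230 in microplastic libraries, and for mRNA fragments, at 3.86% ± 0.769 and 2.96% ± 0.245. The miRNA class also holds reads that match rRNA or tRNA, among them 12574 of 12575 reads of Mir6236-5p, its most abundant feature. Shares, ratios and lengths of this class are thus not those of Dicer products alone. The other classes overlapped between the groups. Small nuclear RNA fragments took 0.905% ± 0.429 in control and 0.537% ± 0.351 in microplastic libraries. In the same order, small nucleolar RNA fragments took 0.483% ± 0.103 and 0.396% ± 0.104, and lncRNA fragments 0.720% ± 0.229 and 0.512% ± 0.198. Y RNA fragments took 0.0403% ± 0.00782 and 0.0453% ± 0.0108, other annotated RNAs 0.352% ± 0.00869 and 0.319% ± 0.0486, and unannotated sequences 26.0% ± 2.90 and 24.2% ± 3.15. For mitochondrial tRNA fragments, miRNA and mRNA fragments the two-sided exact permutation p was 0.1, the smallest that 3 against 3 libraries allow, and 0.367 after adjustment over the 11 classes. Counts per class tested with edgeR called 0 of the 11 classes, with 2 at an unadjusted p under 0.05 and 0 called by limma. These 2 were mitochondrial tRNA fragments, with a log2 fold change of −0.73 (SE 0.25, adjusted p = 0.114), and miRNA, with −0.51 (SE 0.23, adjusted p = 0.240). When reads were weighted to 1 length profile, a setting added after the data were seen, mitochondrial tRNA fragments passed the threshold at −1.05, and miRNA turned to +0.20.

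**Figure D1:**
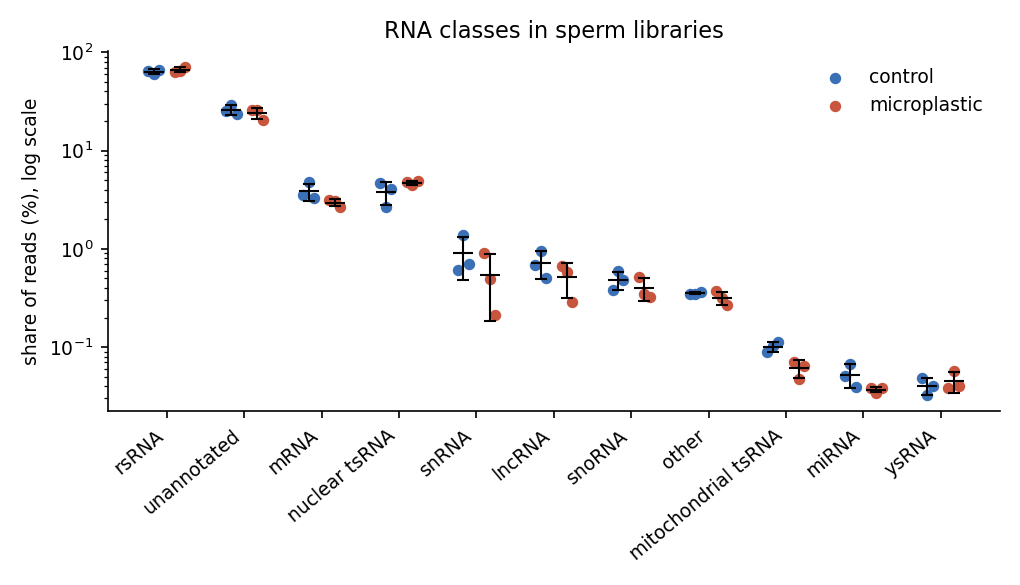
Share of reads per RNA class in the 3 control and 3 microplastic sperm libraries, as a percent on a log axis. Each point is 1 library, and bars give the mean and SD; mitochondrial tRNA fragments, miRNA and mRNA fragments are the classes in which every microplastic point lies below every control point.

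Within rRNA fragments, 5S rRNA, the small RNA of the large ribosomal subunit, made up 7.11% ± 0.0527 in microplastic against 4.68% ± 0.753 in control libraries, and 18S rRNA, the RNA of the small subunit, made up 17.6% ± 0.930 against 22.4% ± 2.99. The transcribed spacers of the 45S precursor took 0.955% ± 0.201 in microplastic and 0.602% ± 0.144 in control libraries. Within nuclear tRNA fragments, those from the 5′ end took 76.5% ± 1.13 in microplastic and 64.7% ± 9.40 in control libraries, while those ending in the CCA tail took 9.72% ± 1.09 and 17.1% ± 6.11, and internal fragments 8.92% ± 0.833 and 13.8% ± 3.13. In each of these parts the groups did not overlap, with an exact permutation p of 0.1 and 0.171 after adjustment over the 12 parts. As shares of all reads, 5S, the 45S spacers and 5′ tRNA fragments again did not overlap, while 18S (11.7% ± 1.17 in microplastic, 14.3% ± 2.16 in control), CCA-end and internal tRNA fragments did. The most abundant 5′ tRNA feature, Glu-CTC, averaged 36167 CPM, against 3062 for the next, shared by Gly-CCC and Gly-GCC. Glu-CTC stood at 50422 ± 8978 CPM in microplastic and 21912 ± 7593 in control libraries. Of 27 tested 5′ features 15 were higher and 12 lower, with a mean log2 fold change of +0.02. The higher 5′ share thus does not describe 5′ fragments in general. The groups overlapped for 28S rRNA (70.2% ± 1.83 in microplastic, 68.7% ± 2.35 in control) and 5.8S rRNA (4.00% ± 1.13 and 3.41% ± 0.558). They also overlapped for mitochondrial 12S rRNA (0.0339% ± 0.00740 and 0.0468% ± 0.0146), mitochondrial 16S rRNA (0.114% ± 0.0201 and 0.140% ± 0.0323) and 3′ tRNA fragments without the CCA tail (4.84% ± 0.996 and 4.35% ± 1.31). Annotated rRNA genes outside these parents held 0.00897% ± 0.00210 and 0.00508% ± 0.000463 of rRNA reads, without overlap.

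Ratios between classes were compared as log2 ratios, microplastic minus control. Nuclear and mitochondrial tRNA fragments together to miRNA differed by 0.80, 5′ to 3′ tRNA fragments by 0.77 and 28S to 18S rRNA fragments by 0.37, with microplastic libraries above all control libraries, and mitochondrial to nuclear tRNA fragments by −1.08, with microplastic libraries below. Each gave an exact permutation p of 0.1, or 0.125 after adjustment over 5 ratios. The 5′ to 3′ ratio counts reads, so among 5′ features it rests most on Glu-CTC, the most abundant. rRNA fragments to all tRNA fragments differed by −0.27, within the spread between libraries (exact permutation p = 0.3).

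**Figure D2:**
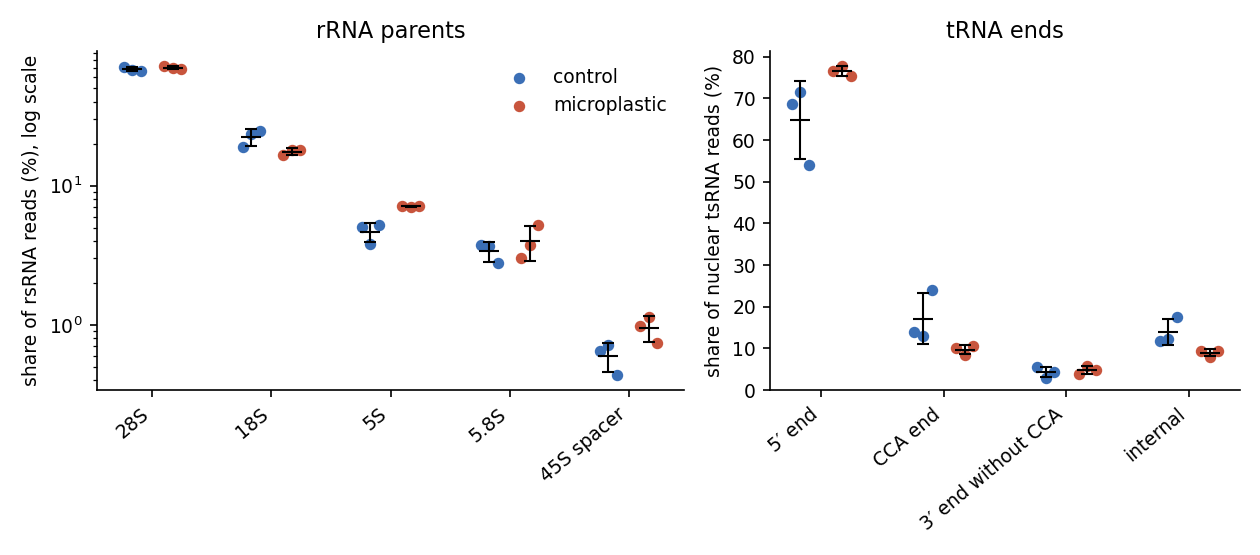
Left, share of rRNA fragment reads by parent rRNA, in percent on a log axis; right, share of nuclear tRNA fragment reads by the end of the tRNA they come from, in percent. Points are the 3 control and 3 microplastic libraries and bars the mean and SD; 5S fragments and 5′ tRNA fragments lie higher, and 18S and CCA-end fragments lower, in all microplastic libraries.

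Reads were longer in the microplastic libraries. Their mean length was 35.2 nt ± 0.368, against 33.6 nt ± 0.0322 in control libraries, and reads of 36 to 45 nt took 60.4% ± 3.42 against 49.2% ± 1.60 of the library. Part of this rise came from the most abundant sequence, a 36 nt fragment of 28S. It took 16.7%, 12.9% and 14.6% of reads in control libraries and 21.9%, 20.6% and 17.3% in microplastic libraries. Short reads took less: 8.52% ± 1.24 against 13.6% ± 1.09 at 15 to 24 nt, and 6.74% ± 0.743 against 11.7% ± 1.78 at 25 to 29 nt, while 30 to 35 nt overlapped (24.4% ± 1.84 and 25.5% ± 0.856). The shift was seen in several classes: rRNA fragments averaged 35.4 nt ± 0.345 in microplastic and 33.9 nt ± 0.120 in control libraries, nuclear tRNA fragments 32.9 nt ± 0.358 and 30.9 nt ± 0.533, miRNA 23.4 nt ± 0.115 and 22.2 nt ± 0.543, mRNA fragments 35.6 nt ± 0.547 and 33.3 nt ± 0.290. In 9 of 11 classes every microplastic library had a longer mean than every control library, and snRNA and mitochondrial tRNA fragments were the exceptions. Among tRNA fragments the 30 to 35 nt range, the size left by cleavage in the anticodon loop, took 78.4% ± 1.07 in microplastic and 67.2% ± 8.86 in control libraries. Each of these differences without overlap had an exact permutation p of 0.1. The adjusted p was 0.125, over 20 length measures for all reads, rRNA fragments, nuclear tRNA fragments and miRNA and over 15 mean lengths for the comparison across classes. This difference in read length moved with the treatment and stands beside every group of RNAs compared here.

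**Figure D3:**
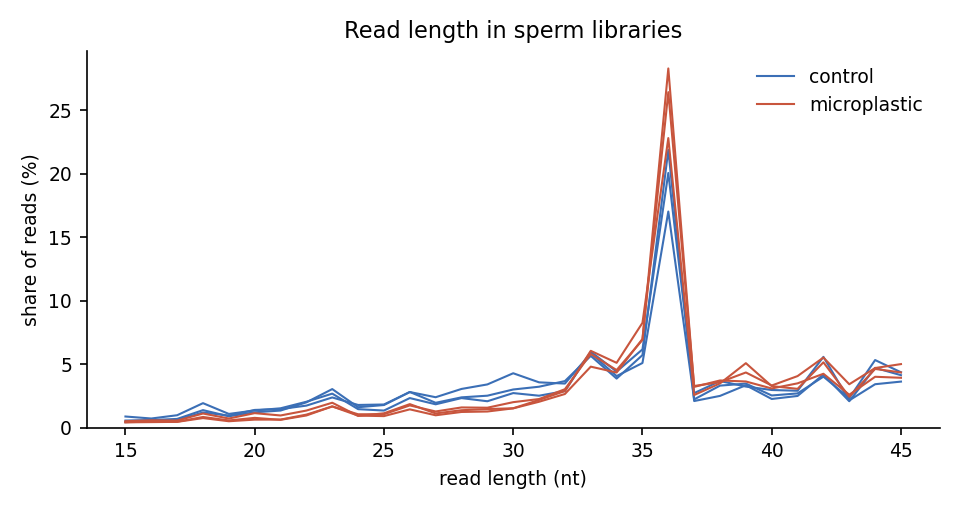
Percent of reads at each read length in nt, 1 line per library, for 3 control and 3 microplastic sperm libraries. The microplastic lines lie above the control lines at 36 nt and below them at each length from 20 to 31 nt.

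Reads were then summed over parent RNAs, or features, and tested one by one. Among the features with the smallest p, the small nucleolar RNA genes Gm22154 and Gm25788, near-identical copies in introns of Pabpc4, which encodes a poly(A)-binding protein, were higher in all microplastic libraries. Gm22154 stood at 8.26 ± 1.29 against 2.35 ± 0.540 CPM, counts scaled to the library (log2 fold change +1.80, SE 0.25), and Gm25788 at 28.7 ± 5.49 against 11.5 ± 1.24 (+1.32, SE 0.24). So was Snord22, a small nucleolar RNA inside its host gene Snhg1, where an annotated exon of some transcript covers it (54.1 ± 12.7 against 17.2 ± 5.75, log2 +1.65, SE 0.32). The same held for Spem2 mRNA, named for spermatid maturation (3.67 ± 0.283 against 1.28 ± 0.448, log2 +1.54, SE 0.29), and the lincRNA Gm31182 (1.98 ± 1.43 against 0.256 ± 0.187, log2 +2.79, SE 0.58). Mir703-5p was lower in all microplastic libraries (0.188 ± 0.203 against 1.73 ± 1.07 CPM, log2 −3.11, SE 0.68). So was the small nucleolar RNA Gm22988 (3.66 ± 0.689 against 7.37 ± 0.710, −1.01, SE 0.22). Ccdc12 mRNA was lower in all of them too (0.559 ± 0.0841 against 1.51 ± 0.248, −1.42, SE 0.34). Gm22988 lies inside the translation factor gene Eif4a1, where an annotated exon of some transcript covers it. Also lower in all of them were Gm22574 in an intron of the cytochrome oxidase subunit gene Cox7c (−3.21, SE 0.78) and the CCA end of mt-Tv, the mitochondrial valine tRNA (−1.98, SE 0.48). None of these 10 passed in edgeR, with an adjusted p of 0.144 for Gm22154 and 0.610 for the others, while DESeq2 called Gm25788 and Snord22. In the GRCm38 assembly, Gm22154 lies on chromosome 4 at 123293152 to 123293282, and Gm25788 on chromosome 4 at 123291344 to 123291474. Snord22 lies on chromosome 19 at 8725866 to 8725991, Spem2 on chromosome 11 at 69816566 to 69818465, and Gm31182 on chromosome 10 at 114875007 to 114885131. Mir703 lies on chromosome 5 at 98475556 to 98475664 inside an intron of Cfap299 on the other strand. Gm22988 lies on chromosome 11 at 69669635 to 69669778, Ccdc12 on chromosome 9 at 110656503 to 110711606, Gm22574 on chromosome 13 at 86044989 to 86045048 and mt-Tv on the mitochondrial chromosome at 1025 to 1093.

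The naming rule also took the most abundant features of the rRNA, tRNA, Y RNA and miRNA classes. None of them passed in edgeR, while DESeq2 called Rny3 and the 5′ fragments of Glu-CTC tRNA. Fragments of 28S rRNA stood at 738133 ± 129452 CPM in microplastic and 512638 ± 126943 in control libraries (log2 +0.53, SE 0.85), and the log2 fold change was +0.09 with total-read scaling. These fragments took 46.5% ± 1.79 of all reads in microplastic and 43.8% ± 2.65 in control libraries, with overlap. 18S rRNA fragments stood at 186429 ± 43987 and 166690 ± 49135, a log2 fold change of +0.16 that became −0.29 when libraries were scaled by total reads. The 5′ fragments of Glu-CTC tRNA stood at 50422 ± 8978 and 21912 ± 7593 (log2 fold change 1.202, SE 0.60), and those shared by Gly-CCC and Gly-GCC tRNA at 2590 ± 1449 and 3534 ± 1533 (−0.45, SE 0.52, or +0.10 with reads weighted to 1 length profile). For mt-Th, the mitochondrial histidine tRNA on the mitochondrial chromosome at 11546 to 11612, internal fragments gave −0.58 (SE 0.39) and CCA-end fragments +0.32 (SE 0.37), the latter −0.09 with total-read scaling. Mir148a-3p, from chromosome 6 at 51269812 to 51269910, stood at 55.2 ± 22.4 and 101.5 ± 28.01 (−0.88, SE 0.37). This value was −0.26 with the length weights and −1.42 with total-read scaling. Mir6236-5p gave +0.52 (SE 0.34), or −0.05 with total-read scaling, and nearly all of its reads also match rRNA or tRNA, so its level is uncertain. The Y RNAs, small RNAs bound by Ro protein, gave +1.33 (SE 0.41) for Rny3, on chromosome 6 at 47781624 to 47781725, and +0.28 (SE 0.38) for Rny1, on chromosome 6 at 47788069 to 47788180, with Rny1 at −0.11 under total-read scaling. The groups overlapped for both Y RNAs. Over 11010 features edgeR called 0, with 814 at an unadjusted p under 0.05 (452 higher, 362 lower), while limma-voom called 0 and DESeq2 18 (16 higher, 2 lower). The libraries of the groups did not overlap in 13.6% of features, where the 10 splits of the libraries into 3 and 3 average about 10%. The percent in the other splits was not computed, so no excess is shown. Leaving out control replicate 3 gave 1 call, a fall of Pde10a, and leaving out microplastic replicate 3 gave 5, falls of Atf3 and Fos and rises of Gm43702, Gm44001 and Gm22154, named here after their values were seen. Scaling by total reads moved the median of all features by −0.47 on the log2 scale, and fold changes are given relative to trimmed-mean scaling.

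**Figure D4:**
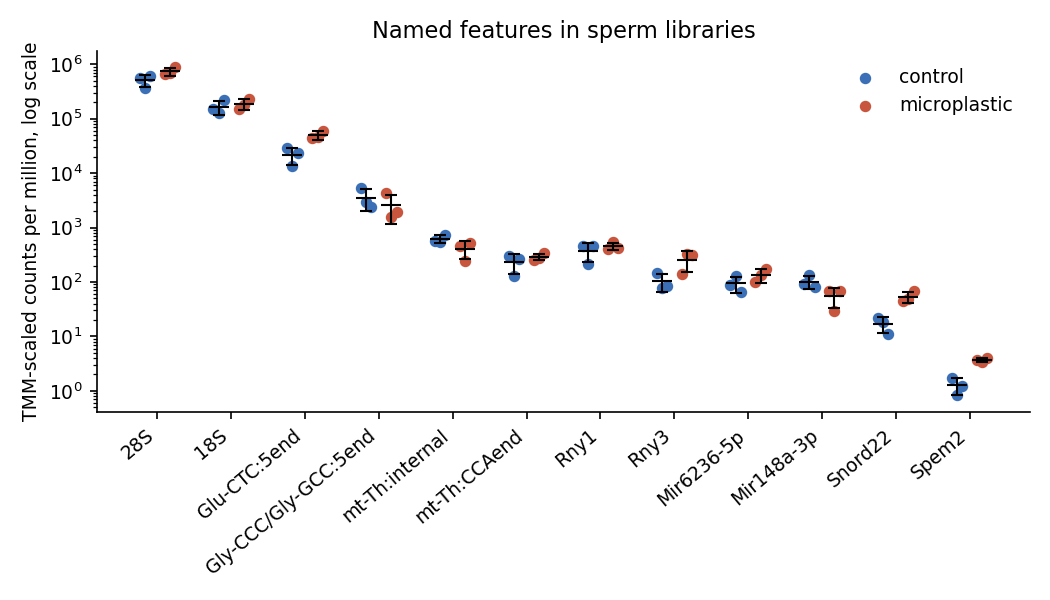
CPM after trimmed-mean scaling, on a log axis, of 12 named features in 3 control and 3 microplastic libraries, with the mean and SD. Glu-CTC 5′ fragments, 28S, Snord22 and Spem2 lie higher in all microplastic libraries, and 18S, Rny1, Mir6236-5p and CCA-end mt-Th fragments turn from higher to lower on average when scaled by total reads. As a share of all reads 28S overlaps between the groups.

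Fixed lists of small RNAs were compared next, and none of their members passed over all features in edgeR, while 14 of the 18 features that DESeq2 called were members (12 higher, 2 lower). The cytoplasmic rRNA fragments (28S, 18S, 5S, 5.8S and 45S spacer) were higher in 5 of 5 features, with a mean log2 fold change of +0.75. The 45S spacer gave +1.18 (SE 0.46) and was called by DESeq2 (adjusted p = 0.00179). 5S gave +1.06 (SE 0.64), 5.8S +0.81 (SE 0.61) and 18S +0.16, which was −0.29 with total-read scaling. It was the 1 list of 18 that camera called with its preset correlation (adjusted p = 0.00101). The call was lost, with an adjusted p = 0.910 with an estimated correlation and 0.597 in fry, which tests whether the list itself moves. Mitochondrial rRNA fragments were higher in 2 of 2 features (adjusted p = 0.501), but 16S went from +0.23 to −0.24 and 12S from +0.08 to −0.40 with total-read scaling. Both Y RNAs were higher on average (adjusted p = 0.138, Rny1 lower with total-read scaling), but the groups overlapped for each. Rny3 had risen when adjusted over the list alone. Of the 5′ tRNA fragments typical of mature sperm, 6 of 11 were higher (adjusted p = 0.746), among them Asp-GTC at +1.04 (SE 0.47), while Gly-GCC gave +0.23, or −0.20 with total-read scaling. Of all 5′ nuclear tRNA fragments 15 of 27 were higher (adjusted p = 0.450). Of the 3′ fragments 33 of 77 were higher (adjusted p = 0.394), with Asp-GTC at +1.34 (SE 0.56) and Tyr-GTA CCA ends at −1.07 (SE 0.70). Their mean was −0.11 and their median −0.13, against an upward direction in camera. Of mitochondrial tRNA fragments 22 of 34 were lower, with a mean of −0.22 (adjusted p = 0.343). In these tRNA lists 0 members passed in edgeR when adjusted over the list alone. Over all features DESeq2 called 6 of their members. Beside Glu-CTC 5′ fragments these were Glu-CTC CCA ends (+1.12, SE 0.33), Leu-AAG CCA ends (+2.003, SE 0.45), other 3′ fragments of Leu-AAG (+1.82, SE 0.49), internal fragments of mt-Tt (+1.67, SE 0.54) and 3′ fragments of mt-Tg (−1.32, SE 0.38), with the edgeR estimates given. Leaving out a single library changed the calls of lists: without control replicates 1, 2 and 3 camera called 8, 4 and 4 lists, and without microplastic replicates 1, 2 and 3 it called 5, 1 and 5.

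Among miRNA lists, the X-linked testis cluster, expressed in male germ cells, was lower in 4 of 4 members with a mean of −0.82 (adjusted p = 0.138), but with reads weighted to 1 length profile Mir470-5p went from −0.12 to +0.55 and the joint 3p arm of Mir465, Mir465b and Mir465c from −0.33 to +0.30. Mir465b-5p, with copies on chromosome X at 66829202 to 66829280 and 66835764 to 66835842, had fallen when adjusted over the list alone (−1.51, SE 0.45). It stood at 0.335 ± 0.145 CPM in microplastic and 1.01 ± 0.298 in control libraries. In the let-7 family, regulators of developmental timing, 3 of 9 were higher and 6 lower. Adjusted over the list alone 1 had risen, Mirlet7i-5p at +0.81 (SE 0.30) with the groups overlapping, and 3 had fallen. Mirlet7a-5p, at −0.62 (SE 0.37), did not pass. The group of miR-10, miR-99, miR-100 and miR-125 was lower in 4 of 6 (adjusted p = 0.263). The miR-17-92 clusters were higher in 2 of 2, with Mir25-3p at +0.48 (SE 0.33) and Mir92-3p at +0.15, which was −0.29 with total-read scaling. In the miR-30 family Mir30d-5p gave −0.71 (SE 0.29) and Mir30a-3p +0.01, or −0.43 with total-read scaling. Mir30a-3p and Mir375-3p, at +0.28 or −0.15 with total-read scaling, were the tested miRNAs of published paternal stress and diet work (adjusted p = 0.558). Of miRNAs that mark other cell types, the epithelial Mir200c-3p, on chromosome 6 at 124718322 to 124718390, had fallen when adjusted over the list alone (−1.62, SE 0.40). Its level was 0.376 ± 0.0839 CPM in microplastic and 1.12 ± 0.210 in control libraries. The other 3 tested members of the epithelial list were Mir200b-3p at −0.76 (SE 0.36), Mir203-3p at +0.66 (SE 0.44) and Mir200a-5p at +0.33, which was −0.15 with total-read scaling. The liver miRNA Mir122-5p, on chromosome 18 at 65248861 to 65248926, had risen when adjusted over the list alone, as its single tested member (+1.28, SE 0.40). The muscle miRNAs Mir133a-3p and Mir143-3p gave +0.98 (SE 0.42) and −0.13 (SE 0.24), and the blood cell miRNA Mir486-5p, shared with Mir3107-5p, gave +0.26, or −0.17 with total-read scaling. The Dlk1-Dio3 imprinted cluster had 1 tested member, Mir127-3p, at −0.07, and of the family of miR-34 and miR-449, 3 were detected and 0 had enough reads to test. The adjusted p of camera was 0.343 for the let-7, miR-17-92, miR-30, epithelial and muscle lists. Over all miRNAs 39 of 76 were higher, with a mean of −0.05, a median of +0.02 and a downward direction in camera (adjusted p = 0.558), and adjusted over the list alone 2 had risen and 2 had fallen. With length weights camera turned upward for all miRNAs (adjusted p = 4.95e-10) and for let-7 (adjusted p = 0.0150) and called 11 lists. DESeq2 called 1 miRNA, Mir5126-3p (+1.77, SE 0.44 in edgeR). Small nucleolar RNAs were higher in 113 of 226 (mean −0.07, median −0.01, adjusted p = 0.668), with 3 risen and 1 fallen when adjusted over the list alone. Snord50a and Snord50b, counted together, stood at 737 ± 356 CPM in microplastic and 260.3 ± 55.2 in control libraries (+1.502, SE 0.43) and were called by DESeq2 (adjusted p = 0.00523). So were Gm23130 (+1.59, SE 0.39), Snord14c with Snord14d (−1.37, SE 0.39), Gm25788 and Snord22. Small nuclear RNAs were higher in 27 of 48 (mean +0.01, median +0.11, adjusted p = 0.343), with 0 passed when adjusted over the list alone. Weighting reads to 1 length profile turned the sign of 13 of 68 named features, among them Mirlet7a-5p (+0.04, or −0.01 with weights from mRNA fragments that share no stretch with rRNA), Mir10a-5p (+0.32), Mir99a-5p (+0.17), Mir125b-5p (+0.35) and Mir143-3p (+0.60).

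Single sequences were compared because fragments of 1 parent can move apart. Of 56602 unique sequences tested in edgeR, 356 rose and 452 fell in the microplastic libraries. Only 1 call was left with reads weighted to 1 length profile, 1 with a trend on length and GC content removed and 3 with a minimum of 100 reads. The risen sequences averaged 39.6 nt ± 5.95 with a GC content of 65.7% ± 10.96, and the fallen ones 26.4 nt ± 4.87 with 47.1% ± 7.56. Among rRNA fragments 118 rose and 265 fell. Of the called ones 29 of 151 from 18S, 65 of 172 from 28S, 3 of 37 from 5.8S and 16 of 17 from 5S rose, and the others fell. Y RNA fragments rose in 12 of 110 and fell in 0. Of sequences assigned to mRNA 4 rose and 14 fell, of lncRNA 0 and 8, and of small nucleolar RNA 0 and 3. Of small nuclear RNA 2 rose and 3 fell, of other annotated RNAs 2 and 2, and of unannotated sequences 215 and 156. These classes do not count separate RNAs. Of the 4 risen mRNA sequences 2, assigned to Tmem38b, shared a stretch of at least 15 nt with 5S rRNA, as did nearly all reads of Tmem38b, which DESeq2 called as a feature. Of the unannotated sequences 187 of 215 risen ones and most of the fallen ones shared such a stretch with rRNA, 121 of the risen ones with 5S, and of lncRNA 3 of 8 fallen ones. Such reads made up 10.8% ± 1.05 of mRNA reads in microplastic and 5.28% ± 1.45 in control libraries, and without them mRNA fragments took 2.64% ± 0.247 and 3.66% ± 0.789 of all reads, again without overlap. Nuclear tRNA fragments had 2 risen and mitochondrial tRNA fragments 1 risen and 1 fallen, and of miRNA sequences edgeR called 0, with 22 at an unadjusted p under 0.05.

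The most abundant risen rRNA fragment was a 38 nt sequence from the 5′ end of 28S, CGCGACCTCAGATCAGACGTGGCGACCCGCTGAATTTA, at 6427 ± 341.2 against 2213 ± 376.8 CPM (log2 +1.54, SE 0.35, adjusted p = 0.0497). It was followed by a 44 nt sequence that ends at the 3′ end of 5S (positions 76 to 119), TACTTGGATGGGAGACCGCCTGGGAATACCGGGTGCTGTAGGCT, at 2292 ± 472 against 186 ± 218 (+3.63, SE 0.73, adjusted p = 0.0466). The most abundant fallen one came from 18S, AAGAACGAAAGTCGGAGGTTCGAAGACGAT (positions 1029 to 1058 of 1871) at 737 ± 352 against 4561 ± 2771 (−2.63, SE 0.58, adjusted p = 0.0494). The next was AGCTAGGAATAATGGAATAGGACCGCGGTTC (positions 856 to 886) at 235 ± 66.5 against 1152 ± 716 (−2.29, SE 0.49, adjusted p = 0.0482). A fragment from the 3′ side of Leu-AAG tRNA that ends inside the CCA tail, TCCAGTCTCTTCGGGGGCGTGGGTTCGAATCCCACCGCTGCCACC, rose from 1.59 ± 0.759 to 8.47 ± 2.03 (+2.41, SE 0.50, adjusted p = 0.0467). A fragment of mt-Tg, the mitochondrial glycine tRNA (mitochondrial chromosome, 9391 to 9458), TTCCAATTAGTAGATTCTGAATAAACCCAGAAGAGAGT, fell from 5.79 ± 3.36 to 0.456 ± 0.208 (−3.67, SE 0.66, adjusted p = 0.0458). The 5 most abundant sequences of all, 4 from 28S and 1 from 5.8S, were not called. The first, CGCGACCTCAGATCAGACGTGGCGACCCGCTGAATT, stood at 256711 ± 34477 against 169419 ± 18316 (+0.60, SE 0.31, adjusted p = 0.263).

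**Figure D5:**
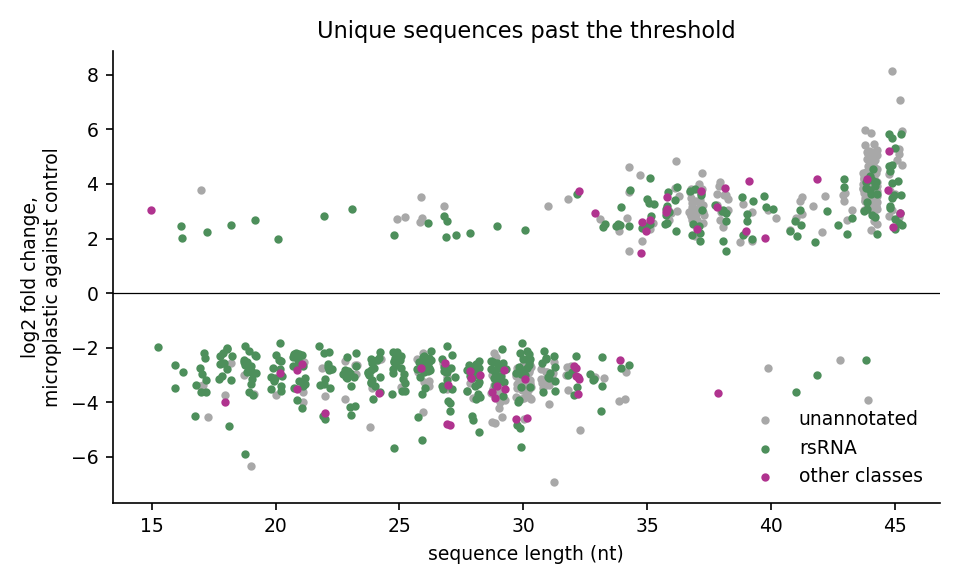
Log2 fold change, microplastic against control, of the 808 called unique sequences by their length in nt, with a small sideways shift of points of equal length. Most risen sequences are over 35 nt long and most fallen ones under 35 nt.

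The adjusted p lay above 0.04 in 318 of the 356 risen and 448 of the 452 fallen sequences. An unadjusted p under 0.05 was found for 13104 sequences. The groups did not overlap in 29.2% of sequences, where the 10 splits of the libraries into 3 and 3 average about 10%. This percent was not computed for the other splits, so it cannot show an excess. DESeq2 called 4384 and limma-voom 15. Scaling by total reads, which moved the median of all sequences by −0.11 on the log2 scale, gave 393 risen and 1179 fallen, so that 25% of calls were risen against 44.1%. Leaving out single libraries moved both the count and its direction. Without control replicate 1 there were 408 calls, 7.84% of them risen, without control replicate 2 there were 0, and without control replicate 3 there were 124 risen and 10 fallen. Without microplastic replicate 1 there were 595, 77.0% of them risen, and without microplastic replicates 2 and 3 there were 2 and 15, all risen. The 7 called sequences taken by the naming rule kept their direction under all of 17 alternatives each but lost the call in 79 of these 119 tests.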

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

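Tests chosen after the result was seen were the weights to 1 length profile, with all mRNA fragments or those that share no stretch with rRNA, the removal of a trend on length and GC content, the exact-match restriction, the 1-mismatch match, the reference without assembled rRNA and tRNA panel, leaving out the pair with extreme TMM factors, and, for the added mRNA lists, leaving out members seen before and shares of all reads. All 109 alternative values of class shares and all 35 of ratios moved by less than the spread between libraries. None of these alternatives used the length weights, which turned the class level of miRNA from −0.51 to +0.20. Of the estimates that passed no threshold in either setting, the sign changed in 66 of 1183 feature values, 16 of them with total reads and 13 with length weights, in 6 of 131 class levels and 6 sequence values, and these were not counted as reversed. The number of called features went from 0 to 18 with DESeq2 and 119 with no filter, and from 0 to 5 when single libraries were left out. Called sequences (808) became 1572 with total reads, 4384 with DESeq2, 15 with limma-voom, 4566 with no filter, 3 with a minimum of 100 reads, 1 with either kind of length weights, 1 with the trend removed, and from 0 to 595 without single libraries. Called classes went from 0 to 1 with length weights. Restriction to 15 to 45 nt changed nothing by construction, ratios have no denominator to change, and genome-matched reads were not run.

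With the replicate block 94 sequences, 0 features, 0 classes and 1 list were called, and 84 of the 94 sequences were among the 808. Features of same-numbered libraries correlated at −0.16, 0.27 and 0.21, and those of other pairs across the groups at −0.35 to 0.24. So few pairs cannot decide whether the numbers pair the samples. Of the 7 called sequences taken by the naming rule 6 lost the call with their direction unchanged, and no call of a feature, class or list changed.

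For lists, camera called 0 with an estimated correlation, 0 with fry, 4 with total reads, 11 with either kind of length weights and 5 without the extreme pair, against 1; single libraries left out gave from 1 to 8. Adjusted p of cytoplasmic rRNA fragments was 0.910 with an estimated correlation, 0.597 with fry and 0.120 without the extreme pair. With total reads it was 0.00249 for 3′ tRNA fragments, 0.0205 for Y RNAs and 0.0315 for small nuclear RNAs. With length weights let-7 (0.0150) and miRNAs (4.95e-10) reversed to higher, and miR-17-92 (0.00420), muscle miRNAs (0.00358), 5′ (0.00891) and 3′ tRNA fragments (0.00138), mitochondrial tRNA fragments (0.00365), Y RNAs (0.0198) and small nuclear RNAs (0.0392) passed. Without the extreme pair 5′ (0.0498) and 3′ tRNA fragments (1.10e-14) reversed, and the miR-10 group (0.000687), mitochondrial tRNA fragments (0.000204) and small nuclear RNAs (0.00179) passed. With single libraries left out the adjusted p ran from 0.0385 to 0.922 for the stress and diet miRNAs, 0.00475 to 0.920 for 5′ and 1.41e-09 to 0.430 for 3′ tRNA fragments (reversed without control replicate 2), 0.00507 to 0.747 for mitochondrial tRNA fragments, 0.0251 to 0.294 for Y RNAs, 0.000510 to 0.843 for small nucleolar RNAs, 0.0135 to 0.747 for the miR-10 group, 0.00207 to 0.450 for the X-linked cluster, 0.0159 to 0.747 for let-7, 0.0449 to 0.364 for epithelial miRNAs and 0.0120 to 0.444 for small nuclear RNAs.

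Counting unique sequences once in place of reads moved these differences, microplastic minus control, by over 1 SD, to smaller sizes except for nuclear tRNA fragments at 36 to 45 nt, up from 0.411 points, and miRNA at 25 to 29 nt, turned from 0.893 points: −3.49 points for all reads at 15 to 24 nt; for miRNA 0.681 nt in mean length and −2.84, −0.991 and 0.671 points at 15 to 24, 25 to 29 and 30 to 35 nt; for nuclear tRNA fragments 1.18 nt and −4.36, −1.67, 0.0825 and 5.95 points at 15 to 24, 25 to 29, 30 to 35 and 36 to 45 nt; for rRNA fragments 0.989 nt and −3.44, −1.72, −0.00634 and 5.17 points. The cause was not tested for any of these moves, except that leaving out libraries leaves fewer samples and the looser filter tests more features.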

Other observations

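Chosen only after the result was seen were the tests of the mRNA lists, their shares of all reads, the splits for features, sequences and these lists, both tests of read length, and, as settings, both kinds of length weights and the removal of a trend. The 4 mRNA lists were written after values of single libraries and the p of 6 members had been seen, so the members not seen before are also given.

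Relative to other mRNA fragments, those of genes expressed in late spermatids were higher in the microplastic libraries. Of 21 genes 20 were higher, with a mean log2 fold change of +0.53 (SEM 0.09), among them Odf1, an outer dense fibre protein of the sperm tail (+0.63, SE 0.26), Oaz3, a spermatid antizyme (+0.81, SE 0.23), Spem1 (+1.05, SE 0.31) and the protamine gene Prm2 (+0.32, SE 0.26). Scaled to the mRNA fragment reads alone, the list took 5041 ± 205.9 CPM in microplastic and 3799 ± 477 in control libraries (exact permutation p = 0.1, the smallest possible, and 0.4 adjusted over 4 lists). As a share of all reads the groups overlapped, at 144.1 ± 17.6 CPM in microplastic and 139 ± 16.7 in control libraries (exact permutation p = 0.6). Camera gave an adjusted p of 4.37e-09 with the preset correlation and 0.260 with an estimated one. The 18 members not seen before averaged +0.39 (SEM 0.06, 17 higher, adjusted p = 1.00e-05 with the preset and 0.457 with an estimated correlation). No member passed alone in edgeR. Genes of the epididymal epithelium, led by Akr1b7 at 579.8 and Crisp1 at 332 CPM, averaged +0.02 (SEM 0.08, 7 of 13 higher), and scaled to the mRNA fragment reads they took 33601 ± 3761 CPM in microplastic and 34472 ± 2913 in control libraries (exact permutation p = 0.8). As a share of all reads they took 953 ± 35.8 CPM in microplastic and 1272 ± 210.5 in control libraries and were lower in every microplastic library (exact permutation p = 0.1, and 0.133 adjusted over 4 lists, as for the next list and the immediate-early genes). Immune cell genes averaged −0.16 with a median of +0.01 (6 of 9 higher), or +0.10 without Tlr8, and camera gave both of these lists an adjusted p of 0.678. Scaled to the mRNA fragment reads the immune list took 3322 ± 991 CPM against 3489 ± 178.1 (exact permutation p = 0.9). As a share of all reads it took 93.2 ± 19.2 CPM against 128.7 ± 19.1, also lower in every microplastic library (exact permutation p = 0.1). No gene is in more than 1 of these lists, and how many of their genes sperm itself expresses was not analysed here. In every library the epididymal list took more of the mRNA fragment reads than the late spermatid list. How much of any RNA class came from cells other than sperm was not measured.

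Fragments of immediate-early response genes, which stress and growth signals induce, were lower in 13 of 14 genes, with a mean of −0.82 (SEM 0.14), among them Atf3 (−1.74, SE 0.44), Fos (−1.07, SE 0.49), Egr1 (−1.12, SE 0.41) and Btg2 (−1.11, SE 0.40). Camera gave an adjusted p of 4.31e-07 with the preset and 0.358 with an estimated correlation, and the 12 members not seen before averaged −0.70 (SEM 0.13). Scaled to the mRNA fragment reads, the list took 1743 ± 1108 CPM in microplastic and 3217 ± 1046 in control libraries (exact permutation p = 0.3). As a share of all reads it took 47.95 ± 26.04 CPM against 117.7 ± 33.9, lower in every microplastic library (exact permutation p = 0.1). Microplastic replicate 3 stood at 3010, within the control range: without it the mean was −1.47, without control replicate 1 it was −0.55 and without microplastic replicate 1 it was −0.52. Over the 10 splits of the 6 libraries, 3 gave a mean as large, the highest other being 1.01 against 0.82 for the groups, and 10 splits are too few for a share under 0.05.

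Reads were longer in the microplastic libraries. A shift of rRNA fragments only is argued against, since the mean length of rRNA fragments differed by −0.773 nt relative to the difference for mRNA fragments, that is by less, and by −0.481 nt without mRNA reads that share a stretch with rRNA. A size selection that acted on every RNA alike may account for the shift: 9 of 11 classes had every microplastic library above every control library. It cannot be told apart from an effect of the exposure on fragment length, because each group had its own libraries and snRNA and mitochondrial tRNA fragments overlapped.

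The called sequences were long and GC-rich when risen and short when fallen. After weighting reads to 1 length profile the median size of their log2 fold changes went from 3.11 (interquartile range 1.02) to 2.61 (0.96). So 83.96% was kept, or 86.8% with weights from mRNA fragments that share no stretch with rRNA, and all kept their direction. A length shift of the size seen in mRNA fragments thus left most of the median fold. Whether size selection is the whole cause cannot be decided this way. The weights, between 0.651 and 1.62, could not remove folds this large, and the sequences were taken for their large folds. GC content and length together stay open, since removing their trend left 2.20 (interquartile range 1.28), or 70.7%. Both corrections left 1 call. The folds were then smaller at a similar median SE (0.63 before, 0.62 and 0.60 after), and the adjusted p had been above 0.04 in 318 risen and 448 fallen sequences. Why the calls were lost was not tested. The groups gave 808 calls and the highest other split 0, with 1 of 10 splits as large, too few for a share under 0.05, and an effect of the exposure stays among the open explanations.

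For the late spermatid genes, size selection is argued against, since 97.9% of the mean difference was kept with length weights. A lower share of other cells could raise them relative to other mRNA and cannot be told apart from an effect on the late spermatid genes themselves: trimmed-mean scaling centres the bulk of features, while as a share of all reads the epididymal list gave a log2 ratio of −0.42, close to −0.38 for all mRNA fragments, and the late spermatid list overlapped between groups. The mean without single libraries ran from +0.39, without control replicate 2, to +0.67, without control replicate 1. The groups gave 0.53 and the highest other split 0.37, with 1 of 10 splits as large, too few for a share under 0.05. A difference in maturity of the sperm, in RNA kept from spermatids or in the samples taken may all remain, and none of them was tested.

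The groups gave 0 calls of features and of classes, so all 10 splits had to give as many, and these counts decide nothing; the highest other split gave 2 features and 0 classes. For fixed lists all 10 gave at least the 1 call of the groups and the highest other gave 9, which may point to a structure among the 6 libraries that does not follow the treatment, or to a preset correlation of 0.01 below the estimated ones, which ran from 0.118 to 0.912; these were not told apart. These splits are too few for a share under 0.05.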
